A study of Mus musculus with 2 samples.

How the data were processed

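Cells of Apc-mutant mouse intestinal organoids were captured on a droplet chip with UMI barcodes, aiming at 3000 cells per sample, per the labels' protocols. The cDNA was amplified for 12 cycles and the sample index PCR had 14 cycles. Reads of 26 and 91 bases were sequenced to a mean of 113705 reads per cell for DBZ and 115754 for the vehicle, per the labels. Cell Ranger 2.1.1, Seurat (version not given) and the mouse build mm10 are named per the submitters' processing notes. The gene annotation, the filters on cells and genes and the normalization settings are not given in the sources used here.

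The authors deposited 1 table of natural log values for both libraries. In every cell, exp(value) - 1 summed to 10000, so the deposited values are the natural log of 1 + 10000 times the gene's share of the cell's UMIs. All 7553435 values above 0 were then whole multiples of 1 step per cell, within a tolerance of 0.01, which recovers the UMIs of each gene and cell. The unit stays a normalized log value, so no count model was run. Cell columns begin with CTRL or GSI. These were read as DMSO (control) and DBZ (a gamma-secretase inhibitor) from the meaning of the names, since the labels give only the treatment titles. The protocol text lists DBZ for both samples, and the titles were followed.

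A gene filter seems to have been applied to each library before merging, from the values: 723 genes are at 0 in every DMSO cell and 282 in every DBZ cell, while no gene was seen in exactly 1 cell of a library. A gene at 0 in all cells of 1 library is therefore written as listed at 0, with no fold and no upper limit. The fewest genes in a cell were 2197 and 2105, so the alternative of at least 1000 genes removed no cell.

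Log values were turned back to a level per 10000 UMIs. The change of a gene is log2 of (mean DBZ + 0.05) over (mean DMSO + 0.05), with each cell weighted equally. The pseudocount understates the change of low genes. Beside it stands the log2 ratio of pooled UMIs with an exact conditional 95% interval. Shares of cells have exact Clopper-Pearson 95% intervals. Intervals cover counting error only, and cells are not replicates. With 1 library per group, no p-value or count of changed genes was made. Shares were also computed after thinning each cell to 5000 UMIs, which left out 0 cells.

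The median change of each of 32 gene lists was set against 10000 random lists of the same size drawn from 20 bins of mean expression, over members seen in at least 1% of the cells of either library. The percentile describes these libraries. Of 454 genes in the lists and markers, 382 were in the table, and the others (Lyz1 and Dclk1 among them) were not used here. The fibroblast and immune lists had 0 genes in the table. Genes named in the text are the 15 highest and 15 lowest changes among genes seen in at least 10% of cells, leaving out Gm, Rik, mitochondrial and ribosomal protein genes and Xist. Added to these are all detected Notch targets, secretory regulators and stem cell genes, Prox1, the strongest 2 to 4 members and most expressed member of other lists described, and 5 leading genes per cluster. Some genes that this rule names are not used here. Genes named outside this rule, chosen after their values were seen, are Muc2, Cxcl1, Ccnd1, Myc, Ephb3, Galnt12, Muc13, Pnliprp2, Mki67, Olfm4, Cck, Gcg and Chga. These lists, the rule, the markers and most alternatives were fixed before the data were examined.

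Cells were clustered with scanpy 1.11.5 and igraph 0.11.9 on the 2000 most variable genes, 30 components, 15 neighbours and Leiden resolution 1 with seed 0, without integration. A first run with single-precision components gave other cluster sizes. It was replaced so that reruns give identical output, its result was known when that was done, and it is kept as an alternative. A later test found that both runs repeat identically on the processor types tried. A cluster took a name where at least 3 of its top 10 genes by fold, among genes in at least 25% of its cells, were markers of 1 class and no class had as many. This rule, the thinning depth, the level of 100 Defa22 per 10000 that makes a cluster defensin-rich, the shares of Lgr5 in cells with and without Prox1, the defensin level without the enteroendocrine-like cluster, and the choice of lists treated as main results were set after the data were seen. The unnamed clusters held 75.3% of DBZ cells and 70.9% of DMSO cells. Doublets were called with scrublet at an expected rate of 5%, which marked 2 DBZ cells (0.161%) and 6 DMSO cells (0.620%). So few calls do little to exclude doublets.

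Code was tested on simulated cells drawn from the DMSO profile over 13373 genes, with 200 genes changed. All UMIs were recovered. The right sign came out for 100% of genes at each fold. The pooled 95% interval held the true value for 97.1% of 34 genes raised 1.5-fold, 90.9% of 33 raised 2-fold, 97.0% of 33 lowered 4-fold and 95.5% of 8597 unchanged genes. All simulated cells of a library shared the same profile, so this coverage does not carry over to genes whose UMIs come from few cells. The main log2 change of genes lowered 4-fold was short by a median of 0.50, as the pseudocount implies. Of 400 unchanged lists 4.5% fell outside the 95% range. Their genes were drawn at random, so this does not cover lists whose genes vary together. Each of 3 planted classes of 100 cells was recovered and named. These classes were planted by raising the same marker genes that the naming rule reads. Their recovery checks the code and not the naming of real cells.

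Symbols were matched to GENCODE M21 on GRCm38, the build that mm10 names, for 12968 of 13373 genes, and positions are 1-based. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used, with matplotlib 3.10.9 for figures. Alternatives changed the pseudocount (0.01 and 0.5), the scale, the weighting, the cells, the genes used for scaling, the depth, the list filter and bins, and the clustering settings.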

Results

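Single-cell RNA sequencing was done on mouse intestinal organoids carrying a mutation in Apc, the tumour suppressor whose loss leaves Wnt signalling switched on. Organoids are small cultures grown from intestinal tissue that hold stem cells and their descendants. A DBZ library and a DMSO library were compared. DBZ blocks gamma-secretase, the enzyme that releases the active part of Notch receptors, and DMSO is its vehicle. The labels give 10 uM DBZ and 300 nM 4-hydroxytamoxifen in a protocol text shared by both samples. The comparison asks how cells of Apc-mutant organoids differ between inhibitor and vehicle. There was 1 library per group, so no difference has a replicate check and no test was made between treatments. Every statement compares these 2 libraries, not the conditions, and intervals cover counting error only.

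The table held 1241 cells of the DBZ library and 968 cells of the DMSO library, with 13373 genes. The labels speak of 3000 cells per sample. A median cell had 10901 UMIs (unique molecular identifiers, which count captured transcripts) in the DBZ library, within a range of 5187 to 59745. In the DMSO library the median was 11183 UMIs and the range 5241 to 56915. Median genes per cell were 3193 and 3089. Totals were 16168229 and 13083018 UMIs. Mitochondrial transcripts took a median of 4.68% of UMIs per cell in the DBZ library and 4.40% in the DMSO library. The median log2 change over 8797 genes seen in at least 10% of the cells of either library was 0.11, so the typical gene lay slightly above 0.

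Hes1, the classical transcriptional target of Notch in the intestine, was lower in the DBZ library. Its mean level was 0.851 per 10000 UMIs with DBZ and 3.34 with DMSO, a log2 change of -1.91. Pooled UMIs gave -1.96, with a 95% counting interval of -2.05 to -1.87. Hes1 UMIs were found in 45.4% of DBZ cells (exact interval 42.7 to 48.3%) and in 75.0% of DMSO cells (72.1 to 77.7%). After thinning every cell to 5000 UMIs the shares were 28.0% and 55.2%. Hes1 (chromosome 16, 30064384 to 30067796, plus strand, protein coding) was the 15th of the 15 genes with the lowest changes.

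The Notch target list did not move as a group. Of its 8 detected members, Hes1 included, 4 were higher and 4 lower, and the median of -0.07 stood at percentile 10.96 of random lists. Nrarp had a log2 change of -0.45, Notch3 -0.30 and Sox9 -0.23, while Dtx4 had 0.62, Lfng 0.28, Bcl2l1 0.25 and Hes7 0.09. The counting interval of Hes7 included 0. Nrarp, Notch3 and Hes7 were seen in under 7% of cells, and the pseudocount shrinks their changes. Pooled UMIs gave -1.25 (-1.85 to -0.67) for Nrarp, from 39 DBZ and 75 DMSO UMIs. For Notch3 they gave -1.11 (-1.98 to -0.28), from 20 and 35 UMIs, and for Hes7 0.69 (-0.61 to 2.13), from 16 and 8. Olfm4, a stem cell gene that Notch activates, was listed at 0 in every DBZ cell and was seen in 7 DMSO cells, so no fold is given. Notch receptors and ligands had a median of 0.09 (percentile 46.5), and gamma-secretase subunits 0.17 (percentile 72.3).

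**Figure D1:**
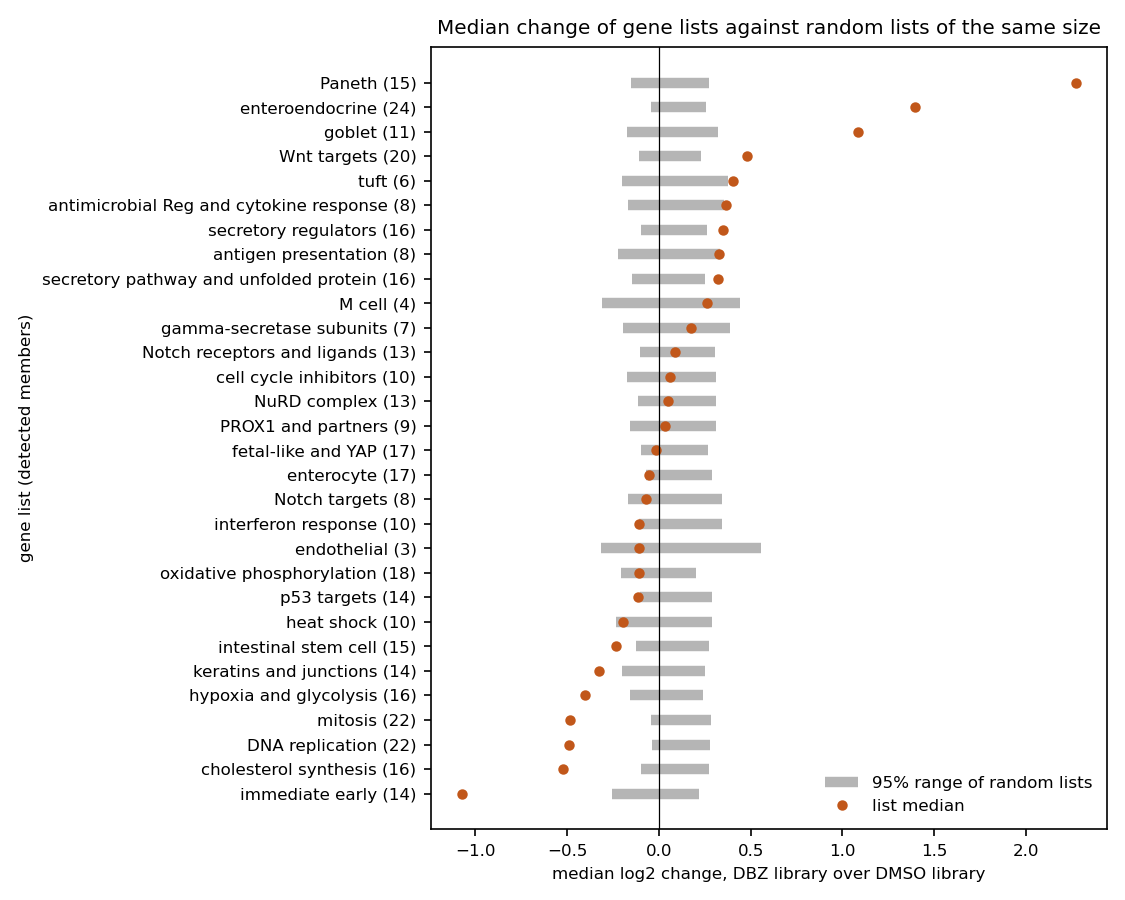
Each point is the median log2 change (DBZ library over DMSO library) of the detected members of a gene list, whose number is in brackets, and each grey bar is the 95% range of 10000 random lists of the same size and similar mean expression. The Paneth list (2.27), enteroendocrine list (1.39) and goblet list (1.08) lie furthest to the right and the immediate early list (-1.07) furthest to the left.

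Transcripts of the secretory lineages were higher in the DBZ library. The Paneth list had a median log2 change of 2.27 (14 of 15 members higher), the enteroendocrine list 1.39 (24 of 24 higher) and the goblet list 1.08 (9 of 11 higher). Each stood at percentile 100 of random lists. Among the members counted as higher, 1 Paneth, 6 enteroendocrine and 1 goblet gene were listed at 0 in DMSO cells. Leaving them out gave medians of 2.25, 1.39 and 1.11, each still at percentile 100. Without the Paneth-like, enteroendocrine-like and defensin-rich clusters the medians were 0.864, 0.468 and 0.697. Within single classes the differences were smaller. The Paneth list had 0.41 in Paneth-like cells (78 DBZ and 13 DMSO cells). The enteroendocrine list had 0.20 in enteroendocrine-like cells (96 and 33). High levels of these same genes helped to form and name the clusters, so smaller differences inside them were largely set in advance. Outside the secretory clusters, in clusters 0, 5 and 6, the Paneth median was 1.32, 1.03 and 0.78 and the enteroendocrine median 0.88, 0.31 and 0.30. Free RNA, set loose by secretory cells, can also give such differences, as the DBZ library had 206 defensin-rich cells and the DMSO library 24. These medians therefore do not show that cells of clusters 0, 5 and 6 made the transcripts. Among Paneth cell products, Defa24 had a mean of 70.7 per 10000 with DBZ and 12.2 with DMSO (log2 change 2.53), Mptx2 had 2.72 (2.13 without the cell with its highest level, which gave 35.6% of the DBZ mean) and Defa21 2.49 (2.92 without its highest cell). Defa22, Defa3, Defa17 and Defa20 lay between 2.29 and 2.45. The DMSO means came largely from few cells. The 5 highest DMSO cells gave 44.2% of the mean for Defa22, 82.1% for Defa3, 70.8% for Defa17, 51.5% for Defa20 and 60.8% for Defa24. Without the Paneth-like, enteroendocrine-like and defensin-rich clusters Defa21 had 1.86, Defa22 1.63 and Defa3 1.06, while Defa24 had 2.93, Defa17 2.64 and Defa20 2.32. Alpha-defensin genes are near-identical copies, so the split of their reads among members is uncertain. Pnliprp2 was the Paneth list member that was lower (-1.21).

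Tff3, the trefoil peptide of goblet cells, had the highest level among goblet genes, 14.2 against 1.71 per 10000 (log2 change 3.02, or 4.30 without the Paneth-like, enteroendocrine-like and defensin-rich clusters). Muc2, the main goblet mucin, had only 17 UMIs in 12 DBZ cells and was listed at 0 in DMSO cells. Fcgbp had 2.13 and Spink4 1.495. Galnt12 (-0.49) and Muc13 (-0.28) were lower. Among hormone and granule genes, Nts (neurotensin) had 2.87, Chgb (chromogranin B) 1.93 and Sct (secretin) 1.80. Nts counts as an enteroendocrine gene here, but it led cluster 2 and averaged only 0.0567 per 10000 in the 96 enteroendocrine-like DBZ cells. The 5 highest DMSO cells gave 89.9% of the DMSO mean of Nts. Npy, the gene of neuropeptide Y, had the highest change that could be computed over all named genes, 4.61, with 2.505 against 0.0544 per 10000. Npy was not on the enteroendocrine list and not a leading gene of the enteroendocrine-like cluster. Its level was 9.41-fold that of other cells in cluster 2 and 4.88-fold in cluster 4, both unnamed and mostly of DBZ cells. The DMSO mean of Npy rested on 65 UMIs in 33 cells, and 54.8% of it came from the 5 highest cells. Gip, Cck and Gcg were listed at 0 in every DMSO cell. The Gip mean of 3.01 in the DBZ library came to 91.1% from 1 cell with 4514 UMIs, and without that cell it was 0.269. For Gcg 94.99% of the mean came from 1 cell, and for Cck 46.3%.

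Of the 16 secretory regulators, 13 were higher in the DBZ library and the median was 0.35 (percentile 99.7), but without the 3 members listed at 0 in DMSO cells it was 0.23 (percentile 93.0), inside the random range. It also lay inside with members in at least 5% of cells (percentile 80.0) and without the Paneth-like, enteroendocrine-like and defensin-rich clusters (89.1). Neurog3, which drives enteroendocrine fate, had a log2 change of 1.51, or 0.43 without those clusters. Within the enteroendocrine-like cluster it was not higher, with 2.58 per 10000 in DBZ and 2.93 in DMSO cells. Bhlha15 had 0.86, Foxa2 0.86, Xbp1 0.75, Foxa1 0.42, Creb3l1 0.32, Dll4 0.23 and Foxa3 0.18. For the low genes among them, pooled UMIs gave 2.79 for Bhlha15 (94 DBZ and 11 DMSO UMIs), 1.30 for Foxa2, 0.87 for Creb3l1 and 0.999 for Dll4. Dll1 had 0.09 and Sox4 0.03. Klf4 (-0.57), Hes6 (-0.42) and Creb3l4 (-0.31) were lower, the last with a counting interval that included 0. Atoh1, the factor that starts secretory fate, was seen in 3.22% of DBZ cells, Spdef in 2.18% and Gfi1 in 1.53%, and all of them were listed at 0 in DMSO cells. Genes of protein folding and secretion had a median of 0.32 (15 of 16 higher, percentile 99.7), led by Sdf2l1 (0.82), Xbp1 and Manf (0.59). Sec61b, the most expressed, had 0.51.

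Tuft cell genes had a median of 0.40 over 6 members (percentile 98.6, but 94.35 after thinning and 89.05 at a pseudocount of 0.01), led by Avil (1.30) and Kctd12 (0.89), with 0.47 for Cd24a. Enterocyte genes had a median of -0.05 (percentile 3.93), with Slc5a1 at -0.98 but Reg3b at 0.75. M cell genes (0.26, percentile 86.4, 4 detected) and endothelial genes (-0.11, percentile 12.9, 3 detected) lay inside the random range.

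Prox1, a homeobox gene that Wnt signalling turns on in intestinal tumours, was higher in the DBZ library. Its mean was 9.42 against 5.90 per 10000 (log2 change 0.67). Pooled UMIs, which weight deep cells more, gave 0.79 (0.75 to 0.84). Prox1 lies on chromosome 1, 190118035 to 190170714, minus strand, and is protein coding. Prox1 UMIs were seen in 96.5% of DBZ cells and 89.5% of DMSO cells, or 89.1% and 77.3% after thinning. Ctnnb1, the gene of beta-catenin, had 0.84. The list of PROX1 and its partners had a median of 0.03 (percentile 38.9), or 0.56 (percentile 99.95) over members in at least 5% of cells, and the NuRD chromatin complex 0.05 (percentile 29.96).

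Wnt target genes were higher as a group, with a median of 0.48 and 15 of 20 members higher (percentile 100). Within the shared clusters 0, 5 and 6 the median was 0.43, 0.27 and -0.08, with 12 of 20 members lower in cluster 6. Wif1 had 1.31, Mmp7 1.20 and Notum, a secreted Wnt inhibitor and the most expressed member, 0.81. Mmp7 is also on the Paneth list, and Paneth-like cells took a larger share of the DBZ library. Lower members were Ccnd1 (-1.32), Myc (-0.86), Ephb3 (-0.69), Lgr5 (-0.30) and Ascl2 (-0.26). Of these, Ccnd1, Myc and Ephb3 were named after their values were seen.

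The intestinal stem cell list went both ways, with 10 of 15 members lower and a median of -0.23 (percentile 0.18). Within clusters 0, 5 and 6 the median was 0.11, 0.18 and -0.08, so the lower median over all cells was not seen in 2 of these clusters. Igfbp4 (-1.85), Smoc2 (-1.24) and Cdca7 (-1.22) were lowest, followed by Rgmb (-0.35), Lgr5 (-0.30), Slc12a2 (-0.29), Ascl2 (-0.26) and Sox9 (-0.23). Lrig1 had -0.08 and Hopx -0.01. Tnfrsf19 (0.34), Axin2 (0.48), Msi1 (0.73), Rnf43 (0.79) and Bmi1 (0.93) were higher. Lgr5, the receptor that marks crypt stem cells, had 1.07 per 10000 with DBZ and 1.33 with DMSO. It lies on chromosome 10, 115450311 to 115587780, minus strand. Its UMIs were seen in 55.6% and 60.2% of cells, or 33.6% and 40.3% after thinning.

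Prox1 and Lgr5 UMIs were both seen in 54.1% of DBZ cells against a product of 53.6%, a ratio of 1.01, and in 55.1% of DMSO cells against 53.9%, a ratio of 1.02. Because Prox1 UMIs were in nearly all cells, these ratios could hardly differ from 1. After thinning, Lgr5 UMIs were in 35.6% of DBZ cells with Prox1 (32.8 to 38.5%) and in 17.0% of those without (11.1 to 24.5%). In the DMSO library the shares were 42.1% (38.5 to 45.7%) and 34.1% (27.9 to 40.8%), with overlapping intervals. Prox1 averaged 10.7 per 10000 in DBZ cells with an Lgr5 UMI and 7.84 in those without, and 6.35 and 5.23 in DMSO cells, but cells with Lgr5 UMIs were also deeper (medians of 11651 against 10277 UMIs with DBZ and 11692 against 10317 with DMSO).

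Cell division genes were lower over all cells. All 22 mitosis genes were lower (median -0.49, percentile 0), among them Ccnb1 (-0.92), Cdc20 (-0.85), Ccnb2 (-0.78) and Ube2c (-0.72). Of 22 DNA replication genes 21 were lower (median -0.49, percentile 0), led by Hells (-0.82), Mcm3 (-0.79) and Ung (-0.73), with Pcna at -0.49. Mki67 UMIs were seen in 15.1% of DBZ cells (13.2 to 17.3%) and 17.9% of DMSO cells (15.5 to 20.4%), and after thinning in 8.30% and 8.68%. Cell cycle inhibitors had a median of 0.06 (percentile 42.55).

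Cholesterol synthesis genes were also lower, 15 of 16 with a median of -0.52 (percentile 0). Fdps had -0.997, Idi1 -0.96 and Msmo1 -0.90. Hypoxia and glycolysis genes had a median of -0.40 (14 of 16 lower, percentile 0.01), with Car9 at -1.27, Egln3 at -1.11 and Gapdh, the most expressed, at -0.37. Keratin and junction genes had -0.32 (9 of 14 lower, percentile 0.32), with Cldn15 at -0.94, Cldn4 at -0.92 and Krt8 at -0.81. Immediate early genes, which respond within minutes to growth factors and stress, were lower without exception among 14 members (median -1.07, percentile 0). Fos had 2.27 against 9.11 per 10000 (-1.98), Nr4a1 -1.65 and Atf3 -1.41. Jund, the most expressed, had -0.08. Within clusters 0, 5 and 6 the median was -0.62, -1.21 and 0.35 for immediate early genes and -0.09, -0.31 and 0.35 for keratin and junction genes, where Krt8 had 0.54 in cluster 6. Cholesterol genes (-0.53, -0.84 and -0.27) and hypoxia and glycolysis genes (-0.40, -0.55 and -0.19) were lower in all 3.

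The 15 genes with the lowest changes were Fgfbp1 (-2.56), Prelp (-2.52), Egr4 (-2.51), Gdf15 (-2.38), Amica1 (-2.25), Cited4 (-2.21), Hbegf (-2.15), Cxcl10 (-2.13), Arc (-2.07), H2-Q10 (-2.03), Fos, Egr2 (-1.96), Cyr61 (-1.93), Fosl1 (-1.91) and Hes1. Egr4, Arc, Fos, Egr2 and Fosl1 encode immediate early factors, and Hbegf a ligand of the EGF receptor. Besides Gip and the genes above, the 15 with the highest changes included Ly6d (2.68), Aldh1a2 (2.66), a retinoic acid enzyme, and Irx5 (2.43).

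Clustering of both libraries together gave 12 clusters. The 5 clusters with over 90% of their cells from 1 library held 46.7% of all cells, and 0% when each gene was centred within its library first. Centring takes out every mean difference between the libraries, whether from treatment or from preparation, so that 0% does not tell them apart. Clusters 1 (Cyp2c55 and Notum among the leading genes), 2 (Nts, Aldh1a2 and Ly6d) and 4 (Mt3, Spock2 and Pycr1) held 19.1, 18.6 and 14.1% of DBZ cells, against 1.96, 1.03 and 2.58% of DMSO cells. Clusters 3 (Pnliprp2, Cited4 and Egr4) and 7 (Gdf15, Pmp22 and Egr4) held 21.6 and 18.7% of DMSO cells, against 0.161 and 0.242% of DBZ cells. Cluster 5 (Ifi27l2b, Amica1 and Fgfbp1) held 4.11% of DBZ and 15.2% of DMSO cells, and cluster 6 (Pmp22, Id1 and Lipt2) held 8.62 and 8.68%. These clusters stayed unnamed, as did cluster 8 (Defa21 and Defa22), with 10.3% of DBZ and 1.14% of DMSO cells. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type.

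**Figure D2:**
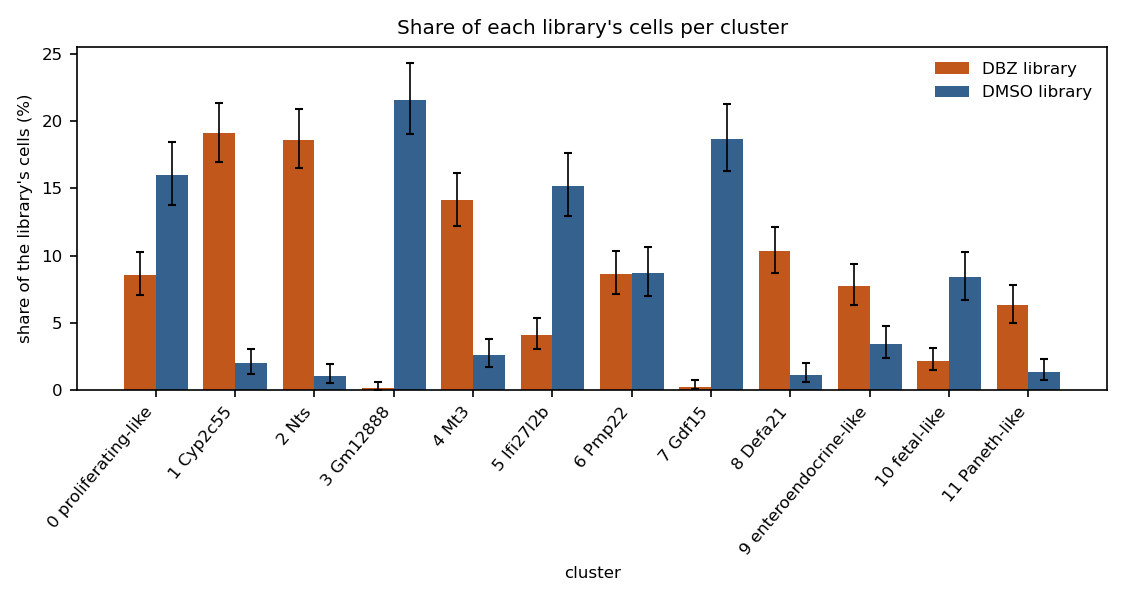
Bars give the share of each library's cells (percent) in each cluster, named by its markers or its leading gene, and lines give exact 95% counting intervals. Clusters 3 and 7 hold mostly DMSO cells, clusters 1, 2, 4 and 8 mostly DBZ cells, and cluster 6 holds 8.62% of DBZ and 8.68% of DMSO cells.

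The named classes differed in size too. The Paneth-like cluster (Defa17, Defa3 and Ang4, with the goblet gene Spink4) held 6.29% of DBZ cells (5.0 to 7.8%) and 1.34% of DMSO cells (0.717 to 2.29%). The enteroendocrine-like cluster (Reg4, Chga and Chgb) held 7.74% (6.31 to 9.36%) and 3.41% (2.36 to 4.75%). These genes also differ between the libraries, so clustering was repeated without the listed Paneth, goblet and enteroendocrine genes and all Defa genes. Other leading genes of these clusters, Reg4 and Gm15284 among them, were not left out. The repeat is therefore not free of the secretory difference. The Paneth-like shares were then 4.43 and 0.826%, and the enteroendocrine-like shares 16.2 and 4.24%. That enteroendocrine-like cluster is a wider class, since it took in 85.6% of the cells of cluster 8 (109 DBZ and 10 DMSO cells), which was no longer a cluster of its own.

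The proliferating-like cluster (Ube2c, Ccnb1 and Nusap1) held 8.54% of DBZ cells (7.05 to 10.2%) and 16.0% of DMSO cells (13.8 to 18.5%). Clustered without replication and mitosis genes, the shares were 7.57 and 9.61%, and the interval of their log2 ratio of -0.34 ran from -0.77 to 0.09. At a finer resolution the class split by library, and the direction turned because 1 part, with 3 DBZ and 87 DMSO cells, lost its name. Cluster 10, with the fetal-like markers Sprr1a and Ly6a beside Reg3g, held 2.18% of DBZ and 8.37% of DMSO cells, but in a first clustering run no cluster took that name. With another seed the fetal-like shares were 1.69 and 2.69%, and without predicted doublets 1.45 and 1.98%, and the intervals of their log2 ratios (-1.57 to 0.22 and -1.46 to 0.57) included 0.

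Hes1 was lower in the DBZ library within each of the 10 clusters that had at least 10 cells of each library, with log2 changes of -1.05 to -2.64. In clusters 0, 5 and 6, which had at least 50 cells of each, the changes were -1.65, -1.42 and -2.05. Their counting intervals excluded 0, while that of cluster 8 (-1.88 to 0.47) did not. Prox1 had 0.64, 0.63 and 0.09 in clusters 0, 5 and 6, and the interval in cluster 6 (-0.05 to 0.23) included 0. Lgr5 was lower in these clusters by more than over all cells, with -1.48, -1.16 and -0.90. In clusters 2 and 4, with 10 and 25 DMSO cells, Lgr5 had 1.18 and 0.54. Within the proliferating-like cluster the mitosis and replication medians were -0.15 and -0.17, in cluster 5 they were 0.11 and -0.02, and in cluster 6 both were higher in the DBZ library (0.57 and 0.36).

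**Figure D3:**
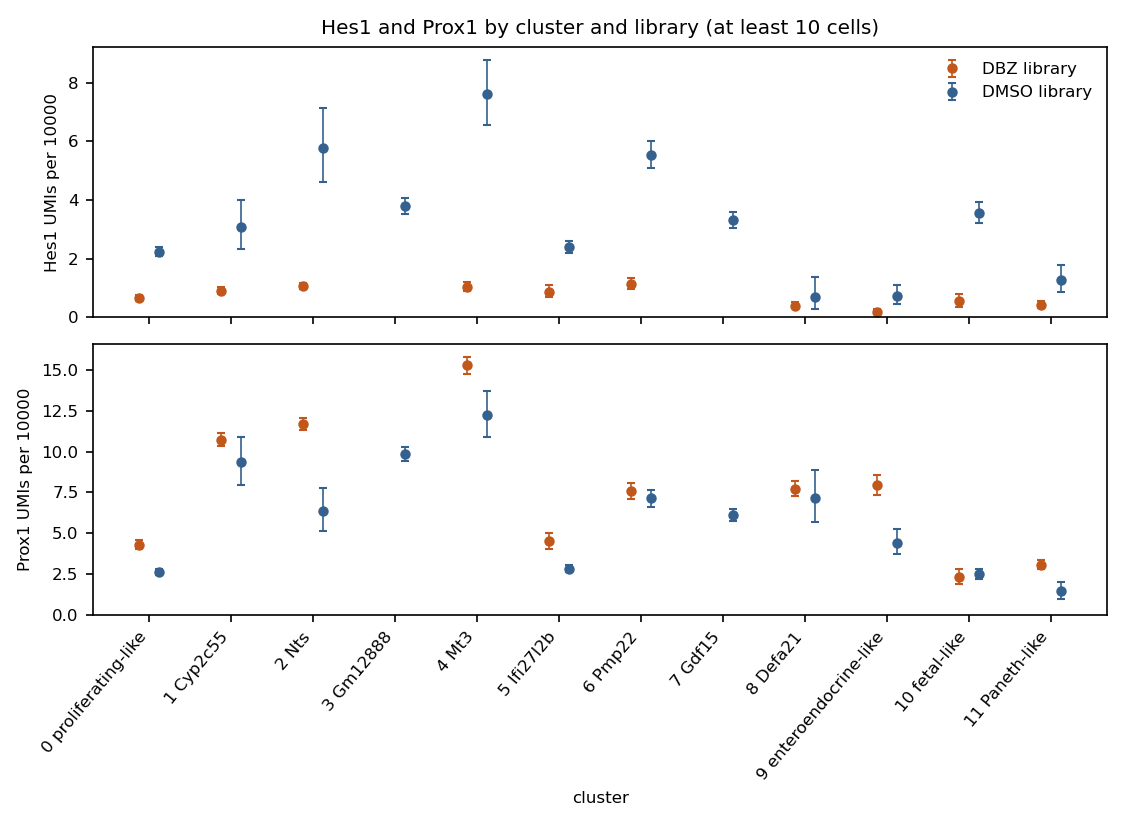
Points give pooled UMIs per 10000 of Hes1 (top) and Prox1 (bottom) in each cluster and library with at least 10 cells, and lines give exact 95% counting intervals. The Hes1 points of the DBZ library lie below those of the DMSO library in each of the 10 clusters with both.

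Alpha-defensin transcripts were concentrated in clusters 8 and 11, which held 92.7% of the 10 Defa genes' UMIs in the DBZ library and 85.7% in the DMSO library. These clusters had 206 DBZ cells (16.6%) and 24 DMSO cells (2.48%). Their level was 1537 per 10000 UMIs with DBZ and 1849 with DMSO, so within them the DBZ library was not higher. Both clusters were picked by their Defa22 level, so similar levels within them were largely set in advance. Outside them the level was 25.2 and 8.53 per 10000, or 21.9 and 4.24 without the enteroendocrine-like cluster, whose 33 DMSO cells stood at 178. Defa24 UMIs were seen in 99.9% of DBZ cells and 62.8% of DMSO cells, including cells of the proliferating-like cluster. Such low counts in other cell types are also what free RNA gives, so the share of cells with a defensin UMI is not a share of Paneth cells. Within the enteroendocrine-like cluster, Chga UMIs were in 72.9% of 96 DBZ cells and 66.7% of 33 DMSO cells, with overlapping intervals.

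**Figure D4:**
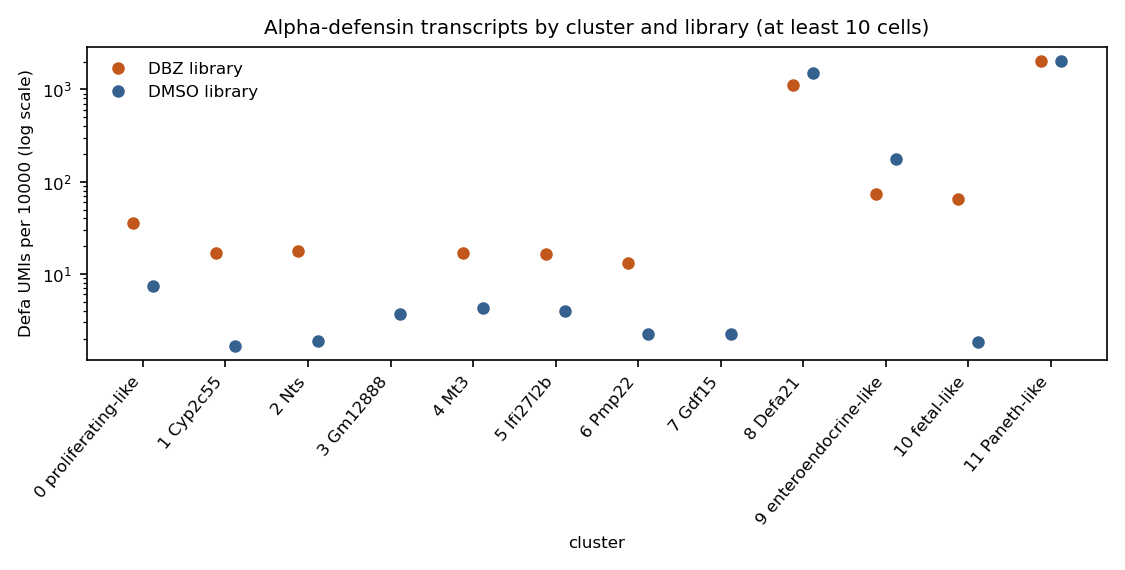
Points give UMIs of the 10 Defa genes per 10000 UMIs (log scale) in each cluster and library with at least 10 cells. Clusters 8 and 11 lie at 1111 or above in both libraries, and elsewhere the DBZ points lie above the DMSO points except in the enteroendocrine-like cluster.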

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

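Alternatives added after the data were seen left out members listed at 0, the Paneth-like, enteroendocrine-like and defensin-rich clusters, or each gene's highest cell. Others used the first clustering run, or clustered without the listed secretory genes and Defa genes. Of the gene changes 526 stayed close, 163 moved and 1 reversed. For lists these counts were 356, 32 and 1, and for cluster shares 32, 19 and 1. Reversed means a change of sign where the value lay beyond its interval or random range. Lists inside that range also changed sign: Notch targets in 2 alternatives, interferon genes in 3, fetal-like and YAP genes in 1 and PROX1 partners in 1. All 4 values within clusters stayed close, and so did 6 Prox1 and Lgr5 ratios, which have little room to move. No setting moved the median of all genes by more than 0.088. The limit of 1000 genes removed no cell and tests nothing. Its values, equal to the main ones, are still counted above as staying close, for genes, lists and the Prox1 and Lgr5 ratios. Few doublets were called. No paired analysis was possible because there is 1 library per group. With DBZ and DMSO in 1 library each, no setting tests library against treatment.

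Low genes depend on the pseudocount and on the mean of logs, which shrinks their values by construction. At a pseudocount of 0.5 the values were -1.505 for Hes1, 0.053 for secretory regulators, 0.403 for goblet, 1.246 for Paneth, 0.533 for enteroendocrine, -0.188 for replication, -0.195 for mitosis and -0.286 for cholesterol genes. At 0.01 secretory regulators had 0.570 and enteroendocrine genes 1.744. As a difference of mean logs they were -0.938 for Hes1, -0.155 for Lgr5, 0.181 for Wnt targets, 0.0260 for secretory regulators, 0.126 for goblet, 0.278 for Paneth, 0.101 for enteroendocrine, -0.0860 for replication, -0.0678 for mitosis, -0.166 for cholesterol and -0.784 for immediate early genes. The secretory regulators lay inside the random range at 0.5. Pooled UMIs gave Prox1 0.788.

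Without the secretory clusters Hes1 had -1.713, Prox1 0.781, goblet genes 0.697, Paneth 0.864, enteroendocrine 0.468 and mitosis -0.262, and Lrig1 reversed to 0.0387. Scaling without the 50 highest genes gave 2.053 for Paneth and 1.578 for enteroendocrine genes. With members in at least 5% of cells, enteroendocrine genes had 1.617 and Reg and cytokine genes reversed to -0.0237, as fewer members counted. Shares after thinning (DBZ, DMSO) were 28.0 and 55.2% for Hes1, 89.1 and 77.3% for Prox1, and 33.6 and 40.3% for Lgr5, lower because depth was removed.

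The log2 ratio of proliferating-like shares reversed to 3.449 at resolution 1.5, where a part with 3 DBZ and 87 DMSO cells lost its name, and was -0.455 with library centring and -0.343 without replication and mitosis genes. The enteroendocrine-like ratio was 1.983 at resolution 0.5 and 1.935 without secretory genes. The fetal-like ratio was -0.861 at resolution 1.5, -1.233 with 1000 genes, -0.831 without replication and mitosis genes, -0.667 with seed 1, -0.922 without secretory genes and -0.443 without doublets, and no cluster took that name with 15 components, centring or in the first run. Cells in clusters over 90% from 1 library were 62.0% at resolution 1.5, 74.6% with 1000 genes, 50.2% with 15 components, 0% with centring, 68.5% with seed 1, 52.6% without secretory genes, 53.1% in the first run, 58.3% without cells over 10% mitochondrial and 42.3% without doublets. The cause of these was not tested beyond what is stated.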

Other observations

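Other gene lists lay near the edge of their random ranges or inside. Reg and cytokine genes had 4 members higher and 4 lower, with Lcn2 at 2.40, Reg4 at 0.94 and Cxcl1 at -1.01. Their median log2 change of 0.36 (percentile 97.8) fell inside the range at a pseudocount of 0.5 (percentile 58.2), as a difference of mean logs (61.3) and with members in at least 5% of cells (20.95), among other settings. Antigen presentation genes had 0.32 (percentile 97.1), inside the range, with Cd74 at 1.03, H2-K1 at 0.38 and B2m at 0.32, and lay outside it in 4 settings. p53 targets had -0.11 (percentile 2.06, but 2.55 from pooled UMIs), with Pmaip1 at -1.03, Cdkn1a at -0.79 and Bax at 0.02. Interferon genes (-0.11, percentile 2.63) lay at the edge of the range, but had 0.20 (percentile 66.2) over members in at least 5% of cells, and oxidative phosphorylation genes (-0.11, percentile 13.74) inside.

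Fetal-like and YAP genes had a median near 0 (-0.01, percentile 13.3), or -0.25 (percentile 0.15) over members in at least 5% of cells, and members went far apart. Cyr61 (-1.93), Ankrd1 (-1.75) and Areg (-1.48) were lower, and Ly6d (2.68) and Clu (2.29) were higher. Ly6d and Clu were leading genes of cluster 2, with 18.6% of DBZ and 1.03% of DMSO cells. Sprr1a and Ly6a led cluster 10, with 2.18 and 8.37%. Lgr5 also differed in direction between clusters, from -1.48 in the proliferating-like cluster to 1.18 in cluster 2, where only 10 DMSO cells stand behind the value.

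The tests of free RNA, of the mix of clusters and of handling stress were chosen after the results were seen. So were the use of trimmed cells for free RNA and the reading of the heat shock test over settings.

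Most clusters held cells mainly of 1 library. A shift of the whole library could produce this: in the shared clusters 0, 5 and 6, at most 0.32 of the neighbours from the other library that even mixing gives were found, as such a shift requires. In the other clusters the ratio ran from 0.39 to 2.16, where the highest values come from clusters with few cells of 1 library. A difference in UMIs per cell is argued against, since thinning to 5000 UMIs left 53.1% of cells in clusters over 90% from 1 library, against 46.7% unthinned, though settings alone gave 42.3 to 74.6% without centring. Treatment and library preparation remain open, as each treatment has 1 library.

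Defensin UMIs were found in nearly all DBZ cells. Free RNA from Paneth-like cells as the only source would give every other cluster a similar ratio of Defa24 to Defa22, but that ratio spanned 6.71-fold outside the defensin-rich clusters. Without each cluster's richest 10% of cells the span was 2.17-fold, with intervals still apart. That span came from cluster 10 (7.11, from 27 DBZ cells and 36 Defa22 UMIs) over the enteroendocrine-like cluster (3.28). The other clusters lay between 4.05 and 5.41. The possible sources themselves had 4.66 (Paneth-like DBZ cells) and 0.122 (DBZ cells of cluster 8), over all their cells. Those other clusters thus lay near the Paneth-like ratio, as free RNA from Paneth-like cells would give, and far from that of cluster 8. Median Defa levels per cell were similar in all clusters compared outside the defensin-rich ones, 12.3 to 17.4 per 10000, which free RNA would also give. Free RNA for most of these UMIs, with some cells that make defensins in each cluster, stays open, and so do shared reads among the gene copies.

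Immediate early genes were lower in the DBZ library, by -1.07 in the median. A different mix of clusters could account for part of this, since the highest median in the shared clusters was 0.35, but the others were -0.62 and -1.21. With library centring the median was lower in all 12 clusters (-1.27 to -0.37), yet these genes help to define clusters and centring shifts cells between them, so mix and change within cells cannot be told apart. Handling stress before capture raises immediate early and heat shock genes, so more of it in the DMSO library would leave both lower in the DBZ library, and the heat shock median of -0.20 (percentile 3.98) lay just inside the random range of -0.23 to 0.29. By the bound first written, and by medians of 0.06, -0.04 and 0.20 in clusters 0, 5 and 6, that counts against handling stress, but 4 of 13 settings fell below the range, so it was left open.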
